A study of Mus musculus with 6 samples.

How the data were processed

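Per the labels' protocols, total RNA was extracted with an RNeasy kit and biotinylated cRNA was prepared with the Illumina TotalPrep kit for Illumina arrays, of a single colour. The 6 arrays were assigned to GFP shRNA or Ube2o shRNA by their titles, 3 to each. For the Ube2o arrays 1 label names an siRNA where the titles name an shRNA; the titles were followed. The submitters call the fibroblasts of each shRNA independent, without saying whether they came from separate embryos or at what point the cultures were parted, so p-values measure only the spread between these arrays, which may be partly technical.

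The authors deposited a table of probe intensity on a linear scale, which differs in its quantiles between arrays. The lowest value of an array lay between 106 and 121. Scanner software and summarisation are not given in the sources used here. The authors also deposited a series matrix of log2 values. These were found to be quantile normalized, with sorted values the same on all arrays within 0.001, and had the same order of probes on each array as the intensity (Spearman correlation at least 0.999999). Their median was 7.386 on every array. The steps behind the log2 values, and any background correction in them, are not given in the sources used here.

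The planned correction (neqc) and probe filter need detection p-values or negative control probes, which were not used here. In their place the background was corrected with the saddle-point normexp method at an offset of 50, followed by quantile normalization and log2, and all 45281 probes were tested. The use of all probes in that case was set out before the data were examined, together with the test, the lists, the rule for named genes and most alternatives. The normexp setting was then listed as an alternative to neqc, and became the setting reported once the values had been looked at. The offset of 50 compresses changes of dim genes. To tell which probes were above background, the mode of the log2 signal of each array and the spread below it were taken as the background, and a probe with p under 0.05 in that distribution was called above it. A gene not above background on any array of a group is given as a bound, "at least N-fold": the mean of the bright group against the mean, per array, of the higher of the lowest normalized value among probes above background and the dim probe's own value.

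Probes were named from the platform annotation and updated through gene identifiers and accessions of the RefSeq table of GRCm38.p6: 35784 probes had 1 symbol, 0 had several and 9497 had none here. A gene is represented by its brightest probe over the 6 arrays. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Changes are Ube2o shRNA minus GFP shRNA on the log2 scale.

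Genes of 40 lists of pathways and cell type markers were followed. Of these, 39 had at least 5 measured genes and were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. Genes were named by this rule: Ube2o and the AMPK subunits; the 12 largest rises and 12 largest falls among genes past the threshold whose groups do not overlap, leaving out predicted models and unannotated clones; and, per list, up to 4 members past the threshold with the smallest p, or the 1 with the smallest p if none passed. Further members of called lists (Cxcl1, Igfbp3, Timp1, Ccl20, Gstm1, Gsta1, Gsta2 and Cbr1) were named after their values were seen.

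The procedure was tested on simulated data with the real control means and a common spread taken from bright probes. Noise was independent between probes. Of 45281 probes, 200 were changed, drawn from the brighter ones, and the proteasome genes were given a small rise besides. The rates therefore do not cover dim genes. In this comparison 100% of the 4-fold falls, 95% of the 2-fold falls and 97.5% of the 2-fold rises, but 20% of the 1.5-fold falls and 40% of the 1.5-fold rises, were recovered, with 4 false calls. With no probe changed, 0 probes and 0 lists passed. Genes were uncorrelated in that run, so it cannot tell how often lists of correlated genes pass. Alternatives covered the background correction, the scaling, the series matrix values, the moderation, array weights, the replicate number as a block, each array left out, the probe of a gene and the fold threshold. Alternatives added after the data were examined were normexp at the offset of 16, filters on the inferred background, the medians of chromosomes and their subtraction. The offset of 16 itself had been planned, for neqc.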

Results

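RNA from mouse embryonic fibroblasts (MEFs) of the C57BL6 strain, taken from embryos at day 13.5, was hybridised to single-colour Illumina BeadChips. There were 3 arrays of MEFs with a short hairpin RNA (shRNA) against GFP, the control, and 3 arrays of MEFs with an shRNA against Ube2o. UBE2O is a large ubiquitin-conjugating enzyme that also acts as a ubiquitin ligase. The submitters describe the fibroblasts as independent for each shRNA and ask which genes and pathways respond to UBE2O loss, under a series title that links UBE2O to the AMPK catalytic subunit α2. Each array measured 45281 probes, which carried 20289 gene symbols, and the median deposited signal lay between 153 and 174. Between 44.6% and 47.0% of the probes on an array lay above the background inferred from its dim probes. Arrays of the same group correlated at 0.993 to 0.996 on the log2 scale across probes, and arrays of different groups at 0.987 to 0.989. The number of arrays limits the precision of every value.

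Ube2o itself was 2.74-fold lower with Ube2o shRNA. Its normalized log2 intensity was 10.84 ± 0.026 (SD, n = 3) with GFP shRNA and 9.39 ± 0.15 (SD, n = 3) with Ube2o shRNA, a log2 change of -1.45 (SE 0.12, adjusted p = 3.15e-07). Its 1 probe gave deposited signals of 1875, 1961 and 2091 on the control arrays and of 668, 851 and 650 on the Ube2o shRNA arrays, so the groups did not overlap. Among the 7 genes of AMPK, the kinase complex that senses low cellular energy, Prkab2, encoding the β2 subunit, rose by 0.60 on the log2 scale (SE 0.11, adjusted p = 0.00349). Prkaa2, which encodes the α2 subunit, did not pass (adjusted p = 0.327) and lay above background on 0 of 3 control and 2 of 3 Ube2o shRNA arrays, too dim for a fold to be given. Prkab1, Prkag1 and Prkaa1, above background on all arrays, did not pass either, with log2 changes of 0.27, 0.16 and 0.066, while Prkag2 lay above background on 1 array and Prkag3 on 0. With no background correction and in the series matrix values Prkab1 passed as well, so that 2 subunit genes rose. The AMPK subunits as a list were not past the threshold of the list test by camera (adjusted p = 0.174), and passed the rotation test fry (adjusted p = 0.0209).

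**Figure D1:**
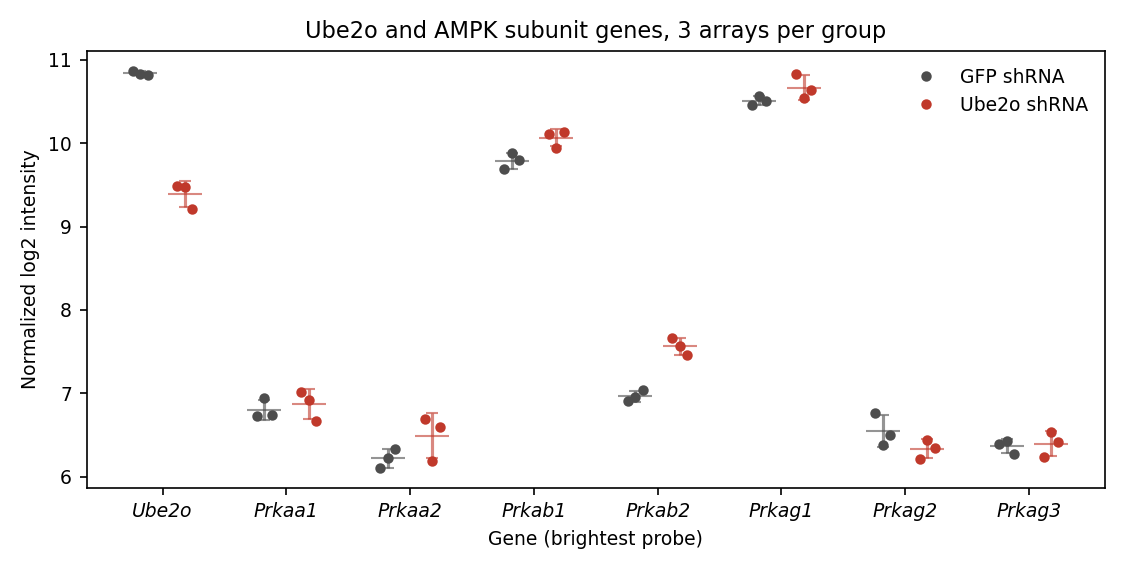
Normalized log2 intensity (vertical axis) of Ube2o and the AMPK subunit genes (horizontal axis), with a point per array, a line at each group's mean and bars of 1 SD (n = 3 arrays per group). The Ube2o shRNA arrays lay near 9.39 for Ube2o against 10.84 in the controls, and among the AMPK subunits Prkab2 alone passed on these values.

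The largest falls with Ube2o shRNA were those of Saa3 and Lcn2. Saa3, an acute-phase serum amyloid protein, fell by 4.72 on the log2 scale (SE 0.13, n = 3 arrays per group, 26.4-fold), and Lcn2, the siderophore-binding lipocalin 2, fell by 4.67 (SE 0.12, 25.4-fold). The log2 change was -3.44 for complement component C3, -3.06 for the protease inhibitor Slpi, -3.38 for the small heat shock protein gene Hspb8, -3.37 for the fetal growth factor gene Igf2 and -2.47 for the insulin-like growth factor binding protein gene Igfbp4. The same group of 12 largest falls held Zfp518b, Stc1, Enpp2 (autotaxin), Mgst2 and Chil1, with log2 changes from -3.50 to -2.47. Zfp518b lay above background on 1 of 3 Ube2o shRNA arrays, and its dimmer probe did not pass (adjusted p = 0.805). The limma adjusted p-values of these 12 genes lay between 1.36e-13 and 1.51e-09. By the rule that chose them, all 3 Ube2o shRNA arrays lay below all 3 controls for each.

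Rises were smaller than these falls. Csmd3 rose by 2.00 on the log2 scale (SE 0.11, adjusted p = 3.52e-09), Gpr149, an orphan receptor gene, by 1.83, and Alcam, an adhesion molecule gene, by 1.63. The homeobox gene Meox2 was at least 2.27-fold higher and the ephrin receptor gene Epha3 at least 2.33-fold higher, since neither lay above background on any control array. Sprr2k, Mfap3l, the corepressor gene Tle1, Capn6, Col15a1, Flrt2 and Rspo3, a gene of the R-spondin enhancers of WNT signalling, completed the 12 largest rises, with log2 changes from 1.21 to 1.43. Of the 4 other probes of Csmd3, 1 passed, with a log2 change of 1.31, and 3 did not. Of the 4 other probes of Epha3, 2 passed, both higher, from control levels near background. Meox2 and Flrt2 lie on chromosome 12, whose genes were higher as a group, and both still passed once the median change of the chromosome was subtracted (log2 change of 1.00 for Flrt2).

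**Figure D2:**
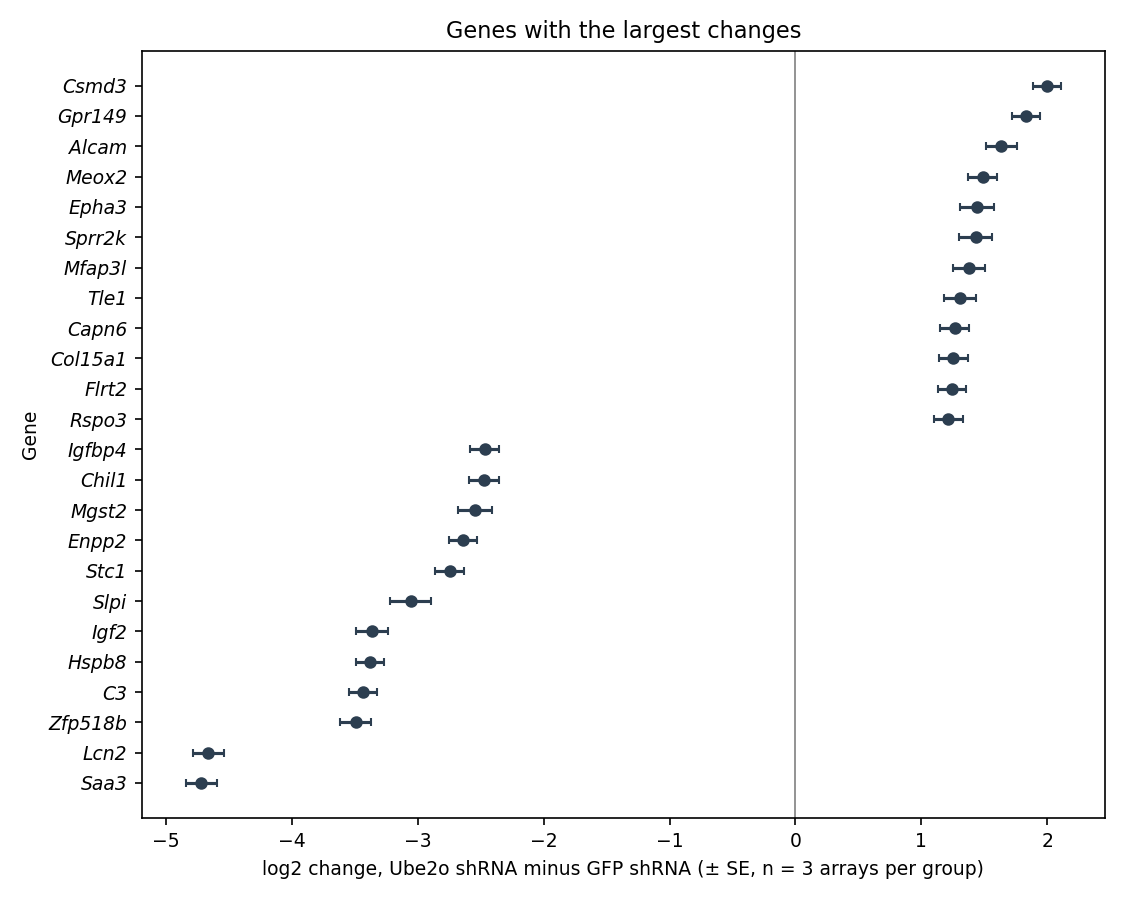
Log2 change with Ube2o shRNA relative to GFP shRNA (horizontal axis, points) with its standard error (bars, n = 3 arrays per group) for the 12 genes with the largest rises and the 12 with the largest falls (vertical axis). Saa3 and Lcn2 lay at -4.72 and -4.67, and the largest rise, that of Csmd3, at 2.00; the values of Meox2 and Epha3 are fitted changes of genes whose control arrays were not above background.

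Across all probes, 2236 of 45281 passed an adjusted p of 0.05 in limma, 1019 higher and 1217 lower with Ube2o shRNA. By the brightest probe of each gene, 591 genes were higher and 801 lower, and 55 genes had a more negative log2 change than Ube2o. The groups did not overlap for 21.4% of all probes, where chance gives 10%. Median scaling in place of quantile normalization gave 567 higher and 1544 lower probes, while with no background correction 2024 were higher and 1942 lower, in the series matrix values 2011 and 1930, and with the filter on all 6 arrays 1930 and 1742, so which direction is more frequent depends on the processing. The count was 584 with a background offset of 16 and 1445 without the array of GFP shRNA replicate 1, and 56 of the 114 called named genes other than Ube2o did not pass with the offset of 16. Of the genes with several probes, 5 had probes called in both directions (H2bc21, Inip, Nme7, Nsd2 and Xpr1, named after their values were seen).

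Several secreted inflammatory genes were lower with Ube2o shRNA. Of 25 measured genes of the list of senescence and secreted inflammatory factors, 8 fell and 0 rose. The interleukin gene Il6 fell by 1.63 on the log2 scale (SE 0.12, n = 3 arrays per group), and the log2 changes of the chemokine genes Ccl2, Ccl7 and Cxcl1 were -1.55, -1.52 and -1.49. Those of the insulin-like growth factor binding protein genes Igfbp4 and Igfbp3 were -2.47 and -1.33. Timp1, an X-linked metalloproteinase inhibitor gene, fell by 0.47 and no longer passed once the median change of its chromosome was subtracted (adjusted p = 0.14), and Ccl20, which was not above background with Ube2o shRNA, was at least 1.12-fold lower. Adjusted over the list alone, 11 genes fell and 2 rose. The list was lower as a group by camera (median log2 change -0.19, adjusted p = 0.000137), with an adjusted p = 0.397 with an estimated correlation. Its median was -0.33 with filters on inferred background and -0.11 with probes averaged. Among macrophage and leukocyte markers 3 of 17 genes fell too, Cd74, Aif1 and Cd14, and 12 of the 17 did not lie above background on all 3 control arrays.

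Genes of antioxidant and detoxifying enzymes moved both ways. Of 24 measured NRF2 target genes, 8 fell and 2 rose. The glutathione S-transferase gene Gsta4 fell by 1.72 on the log2 scale (SE 0.12, n = 3 arrays per group), Gstm1 and Gsta1 had log2 changes of -0.79 and -0.59, while Gsta3 was at least 1.69-fold lower and Gsta2 at least 1.62-fold lower. The log2 changes of the carbonyl reductase genes Cbr3 and Cbr1 were -1.10 and -0.49, and that of the cystine transporter gene Slc7a11 was -0.53. The dimmer probes of Slc7a11 did not pass (log2 changes from -0.006 to 0.104). The 2 genes that rose were Nqo1, encoding a quinone reductase (log2 change 1.04, SE 0.12, adjusted p = 2.02e-05), and Hmox1, encoding heme oxygenase 1 (log2 change 0.91, SE 0.12). Adjusted over the list alone, 11 fell and 2 rose. The list was lower as a group (median log2 change -0.12, camera adjusted p = 0.00737), with an adjusted p = 0.397 with an estimated correlation. Without the array of GFP shRNA replicate 1, 5 of its genes fell and the median was -0.18, and with the offset of 16, 4 fell. The median was -0.22 with median scaling, -0.27 with the filter on 3 arrays and -0.076 with probes averaged.

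Of 19 measured genes of fatty acid oxidation and PPAR targets, 3 fell, 0 rose and 16 did not pass. These were Pdk4, a kinase that holds back pyruvate oxidation (log2 change -1.93), the acyl-CoA thioesterase gene Acot1 (-1.86) and the lipase inhibitor gene Angptl4 (-0.68). Adjusted over the list alone, 4 fell. The median log2 change was -0.13 and the camera adjusted p was 0.0109, with an adjusted p = 0.397 with an estimated correlation, and without the array of Ube2o shRNA replicate 3 the camera adjusted p was 0.057. The list did not pass with probes averaged either (median -0.061, adjusted p = 0.0604) or with the stricter filter (adjusted p = 0.0758), and its median was -0.21 with median scaling.

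Genes of DNA replication were higher as a group by camera and histone genes lower, and neither call was kept with an estimated correlation. Of 34 measured G1/S and DNA replication genes, 4 rose and 0 fell, namely the cyclin gene Ccne2 (log2 change 0.83), the flap endonuclease gene Fen1 (0.65), the helicase gene Mcm5 (0.43) and the ligase gene Lig1 (0.40). The 3 dimmer probes of Lig1 did not pass (log2 changes of 0.007, 0.22 and 0.20). Adjusted over the list alone, 8 genes rose and 1 fell. The median log2 change of this list was 0.18 (camera adjusted p = 0.00241), with an adjusted p = 0.397 with an estimated correlation. Fen1 lies on chromosome 19 and still passed once the median change of the chromosome was subtracted (adjusted p = 0.027). With median scaling 2 of the genes rose, the list's median was 0.082 and its camera adjusted p was 0.0808. With no background correction 9 of the genes rose and 1 fell. When any 1 array was left out 2 or 3 rose, Ccne2 and Fen1 each time, without the array of Ube2o shRNA replicate 2 the median was 0.11, and with the offset of 16 only Ccne2 rose. The G2/M genes had a median log2 change of 0.14 over 33 genes and passed camera (adjusted p = 0.00737) with no single gene past the threshold, and had an adjusted p = 0.552 with an estimated correlation. With no background correction 3 G2/M genes rose and 0 fell. Kif2c, the G2/M gene with the smallest p, had a log2 change of 0.35 (adjusted p = 0.103). The call for G2/M genes was lost with median scaling (median 0.064, adjusted p = 0.0967) and without the array of GFP shRNA replicate 1 (adjusted p = 0.115). Of 23 histone genes, 4 fell and 0 rose, with log2 changes of -1.02 for H3c1, -0.60 for H3c4, -0.48 for H2bc12 and -0.44 for H2bc7. H2bc12 and H2bc7 did not pass when any 1 array other than GFP shRNA replicate 3 was left out, and with the offset of 16 only H3c1 did. Adjusted over the list alone, 5 fell. The histone list had a camera adjusted p of 0.00241 at the preset correlation of 0.01, which was 0.0523 without the array of GFP shRNA replicate 1. Its estimated correlation was 0.39, far above the preset, and the camera adjusted p with it was 0.652.

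Lists of energy and lipid metabolism other than fatty acid oxidation did not pass the list test. Glycolysis came nearest (adjusted p = 0.0531), with 2 of 18 genes higher, Pgam1 (log2 change 0.52) and Eno2 (0.43). In fatty acid synthesis 3 of 17 genes rose, Scd2 (0.59), Fads1 (0.44, its dimmer probe at -0.27 and not past the threshold) and Scd1 (0.41). Those 3 genes and Pgam1 lie on chromosome 19, whose genes were higher as a group, and none of the 4 passed once the median change of the chromosome was subtracted. In cholesterol synthesis 1 of 18 genes rose (Msmo1, 0.48) and 2 fell (Ebp, -0.53, and Hsd17b7, -0.53, its dimmer probe at 0.37 and not past the threshold). Among AMPK upstream and mTORC1 pathway components, 2 of 21 rose, the mTORC1 regulators Flcn (0.45) and Rragc (0.42), and 1 fell, the mTOR inhibitor gene Deptor (-0.73). Of the HIF1 targets other than glycolysis, 2 of 19 rose (Hmox1 and the prolyl hydroxylase gene Egln3, 0.70) and 1 fell (the angiogenic growth factor gene Vegfa, -0.64). The pentose phosphate and nucleotide synthesis list had 1 rise (Rrm2, 0.53) and 1 fall (Rpia, -0.47) in 21 genes, oxidative phosphorylation had 1 fall in 32 (Ndufa1, -0.83), and ATF4 targets and amino acid synthesis had 2 falls in 24 (Atf3, -0.58, above background on 1 of 3 Ube2o shRNA arrays, and Slc7a11). The counts adjusted over the list alone were 4 rises and 1 fall for glycolysis, 5 and 1 for fatty acid synthesis, 5 and 2 for cholesterol synthesis, 4 and 6 for HIF1 targets, 2 and 3 for pentose phosphate and nucleotide synthesis, and 1 and 2 for ATF4 targets. They were as over all probes for the AMPK subunits, the AMPK upstream list and oxidative phosphorylation. Whichever array was left out, at most 1 gene rose in each of 3 lists: 0 in the AMPK upstream list except without replicate 2 of either shRNA, 0 in fatty acid synthesis without Ube2o shRNA replicate 1, and 0 in glycolysis without replicate 1 of either shRNA or Ube2o shRNA replicate 2. The call of Rpia was lost without replicate 1 or 3 of either shRNA, that of Msmo1 without GFP shRNA replicate 1 or Ube2o shRNA replicate 3, that of Slc7a11 without replicate 1 of either shRNA or GFP shRNA replicate 3, and that of Hsd17b7 without GFP shRNA replicate 3, while 2 HIF1 targets fell without Ube2o shRNA replicate 2 or 3. With median scaling 0 genes rose in glycolysis, cholesterol synthesis, pentose phosphate and nucleotide synthesis and the AMPK upstream list and 1 in fatty acid synthesis, while 1 glycolysis gene, 3 HIF1 targets and 2 genes of the pentose phosphate list fell. With no background correction the rises and falls were 4 and 1 for glycolysis, 6 and 0 for fatty acid synthesis, 5 and 2 for cholesterol synthesis, 3 and 4 for HIF1 targets, 2 and 3 for the pentose phosphate list, 2 and 3 for ATF4 targets, 2 and 1 for oxidative phosphorylation and 3 and 1 for the AMPK upstream list. With the offset of 16 these lists, the AMPK subunits aside, held 1 rise, among HIF1 targets, and 1 fall, in oxidative phosphorylation.

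Lists of protein turnover, stress and growth also stayed short of the threshold. Of 25 p53 target genes, 5 fell and 0 rose, the death receptor gene Fas (log2 change -0.69), Bbc3 (-0.62), Ei24 (-0.61), Plk2 (-0.54) and Btg2 (at least 1.02-fold lower, named after its values were seen), with a camera adjusted p of 0.215. Cytosolic ribosomal proteins had 1 fall in 29 (Rplp0, -0.56), and ribosome biogenesis and MYC targets had 1 rise (Tfrc, 0.54) and 2 falls (Pes1, -0.76, and Nolc1, at least 1.16-fold lower) in 27. Proteasome genes had 1 rise (Psmc1, 0.46) and 1 fall (Psma7, -0.46) in 29. Ubiquitin-conjugating enzymes other than Ube2o had 1 rise (Ube2d3, 0.48) and 1 fall (Ube2a, -0.56) in 30. The 2 dimmer probes of Ube2d3 did not pass (log2 changes of -0.069 and -0.12). Lysosome and autophagy genes had 4 rises, Hexa (0.64), Uvrag (0.56), Atg5 (0.48) and Atp6v0d1 (0.42), and 3 falls, Ctsz (-0.52), Wipi1 (-0.52) and Tfe3 (-0.45), in 26, with Atg5, Atp6v0d1 and Tfe3 named after their values were seen. In the interferon response 3 of 35 genes rose, Usp18 (0.74), Isg15 (0.71) and Trim30a (0.56), and Irf1 fell (-0.45). The unfolded protein response and heat shock list had 2 rises in 25, Calr (0.57) and Pdia6 (0.42, its dimmer probe at -0.041 and not past the threshold). With the adjustment over the list alone, 7 p53 targets fell and 1 rose, 4 lysosome and autophagy genes rose and 4 fell, 5 interferon response genes rose and 2 fell, and 2 genes of the unfolded protein response list rose and 2 fell. In the same count 3 proteasome genes and 3 ubiquitin-conjugating enzymes rose and 1 of each fell, 2 ribosome biogenesis genes rose and 2 fell, and 1 ribosomal protein gene fell. Counts changed when 1 array was left out. Without replicate 3 of either shRNA 3 p53 targets fell, without any other array 4, and 1 rose without GFP shRNA replicate 1; lysosome and autophagy genes had 2 rises and 0 falls without GFP shRNA replicate 1 and 2 rises and 2 falls without Ube2o shRNA replicate 1 or 2, and interferon response genes had 1 rise without GFP shRNA replicate 1 and 2 without GFP shRNA replicate 3 or Ube2o shRNA replicate 2. The calls of Pdia6 and Nolc1 were lost without any 1 array, that of Irf1 without any but GFP shRNA replicate 1, those of Tfrc, Psmc1 and Psma7 without replicate 1 of either shRNA, GFP shRNA replicate 2 or Ube2o shRNA replicate 3, and that of Ube2d3 without replicate 3 of either shRNA or Ube2o shRNA replicate 1. Calr lost its call without GFP shRNA replicate 1 or Ube2o shRNA replicate 3, Rplp0 without GFP shRNA replicate 1 and Ube2a without Ube2o shRNA replicate 1, and 2 ubiquitin-conjugating enzymes rose without GFP shRNA replicate 2. With median scaling 2 lysosome and autophagy genes rose and 4 fell, 3 interferon response genes rose and 2 fell, 1 gene of the unfolded protein response list fell and none rose there or among proteasome, ubiquitin-conjugating and ribosome biogenesis genes. With no background correction 4 lysosome genes rose and 5 fell, 5 interferon response genes rose and 1 fell, the unfolded protein response list had 4 rises and 2 falls, proteasome genes and ubiquitin-conjugating enzymes had 3 rises and 1 fall each, ribosome biogenesis had 3 rises and 3 falls, ribosomal proteins had 2 falls, and 1 p53 target rose and 7 fell. With the offset of 16 all these lists held 1 call, a p53 target that fell.

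Genes of the fibroblast programme changed singly and in both directions. TGF-beta and myofibroblast genes had 5 rises, Myl9 (log2 change 0.86), Actg2 (0.75), Ccn2 (0.56), Tagln (0.52) and Tpm2 (0.52), and 3 falls, the receptor genes Tgfbr1 (-0.89) and Tgfbr2 (-0.66) and Ankrd1 (-0.78), in 24. BMP targets had 3 rises, Id2 (1.13), Hey1 (0.76) and Grem1 (0.65), and 2 falls, Msx1 (-0.99) and Id4 (-0.83), in 20. Among 35 collagens and extracellular matrix genes, Col15a1 rose (1.25) and Fbln1 fell (-1.73). Among 18 mesenchymal and epithelial transition genes, Prrx1 rose (0.46) and the gelatinase gene Mmp9 fell (-0.87). Of 30 Hox genes, 4 rose, Hoxc6 (1.08), Hoxa7 (0.81), Hoxc9 (0.55) and Hoxb5 (0.54), and Hoxd4 fell (-0.57), with a camera adjusted p of 0.0727. Among 17 imprinted growth genes, Slc38a4 rose (1.03) and Igf2 fell (-3.37). Ccn2, Tagln, Tpm2, Tgfbr2, Grem1 and Hoxd4 were named after their values were seen. Counts adjusted over the list alone were 5 rises and 6 falls for TGF-beta and myofibroblast genes, 3 and 2 for BMP targets, 2 and 3 for collagens and matrix, 2 and 1 for the transition genes, 5 and 1 for Hox genes, and 1 and 2 for imprinted genes. The call of Prrx1 was lost without any 1 array other than Ube2o shRNA replicate 3, that of Hoxb5 without replicate 2 of either shRNA, GFP shRNA replicate 3 or Ube2o shRNA replicate 1, and no Hox gene fell without GFP shRNA replicate 1 or any 1 Ube2o shRNA array. Without Ube2o shRNA replicate 2, 2 genes fell among collagens and matrix, as without GFP shRNA replicate 1, and 2 among imprinted genes. With median scaling 3 genes fell among collagens and matrix, 2 among imprinted genes and no transition gene rose, and with no background correction there were 5 rises and 4 falls for collagens and matrix, 4 and 1 for the transition genes, 6 and 6 for TGF-beta and myofibroblast genes and 1 and 2 for imprinted genes. With the offset of 16, TGF-beta and myofibroblast genes had 2 rises and 1 fall, and 1 Hox gene rose.

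Markers of other cell types gave few calls. Of 17 macrophage and leukocyte markers, 3 fell, Cd74 (log2 change -2.17), Aif1 (-0.74) and Cd14 (-0.57), and 6 of the 17 lay above background on at least 3 arrays, with a camera adjusted p of 0.0935. Of 13 fibroblast markers, Prrx1 rose and Pdgfra fell (-0.76). Endothelial markers had 1 fall in 12 (Flt1, -0.85), adipocyte markers 1 fall in 10 (Lpl, -0.99), and epithelial and keratinocyte markers 2 falls in 15 (Trp63, -1.02, and Krt7, -0.44, above background on 1 of 3 Ube2o shRNA arrays). Skeletal muscle markers had 1 rise (Acta1, 0.74) and 1 fall (Des, -0.65) in 20, and smooth muscle and pericyte markers had 1 rise (Smtn, 0.49) and the same fall in 12. Neural and glial markers had 2 rises, Map2 (0.69) and Nes (0.51), and 1 fall, Gap43, which was at least 1.32-fold lower, in 13. No gene passed among 11 erythroid markers (smallest p for Slc4a1, adjusted p = 0.193), 10 chondrocyte and bone markers (Sox9, adjusted p = 0.337) or the 4 measured Y-linked genes (Usp9y, adjusted p = 0.701), which were too few for the list test. Adjusted over each marker list alone, 2 fibroblast markers rose and 2 fell and 1 skeletal muscle marker rose and 3 fell, and the counts of the other marker lists were as over all probes. The call of Krt7 was lost without any 1 array other than Ube2o shRNA replicate 2, that of Nes without any other than GFP shRNA replicate 1, that of Smtn without replicate 1 or 3 of either shRNA, and that of Gap43 without GFP shRNA replicate 2 or 3 or Ube2o shRNA replicate 1. Without Ube2o shRNA replicate 2, and with median scaling, 2 fibroblast markers fell, with median scaling no fibroblast or smooth muscle marker rose, and with no background correction 2 fibroblast markers rose and 2 fell. With the offset of 16, 1 leukocyte marker and 1 epithelial marker fell, and 1 neural marker rose and 0 fell.

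**Figure D3:**
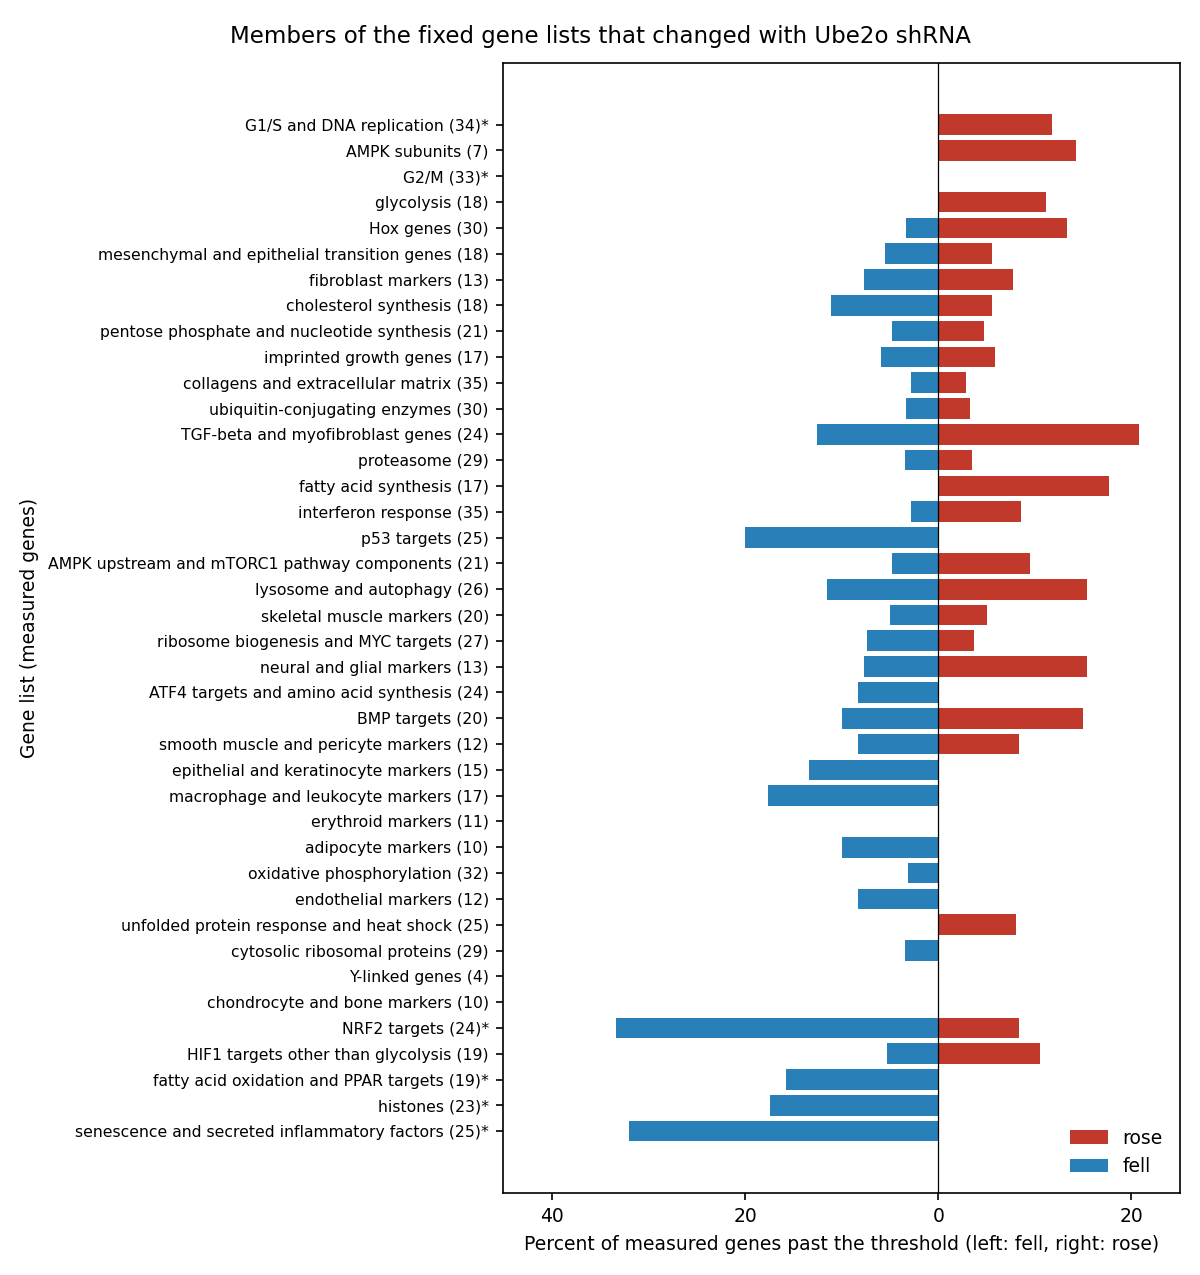
Percent of the measured genes of each list (vertical axis, number of measured genes in brackets) that rose (right, red) or fell (left, blue) with Ube2o shRNA (horizontal axis), ordered by median log2 change; asterisks mark the lists past the camera threshold. The senescence and secreted inflammatory factors had 8 falls in 25 genes, and the G2/M genes passed with no single gene past the threshold on these values.

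In all, 6 of 39 tested lists passed camera, 2 higher and 4 lower, and 0 passed in camera with an estimated correlation, where the smallest adjusted p was 0.397 and 4 lists had an unadjusted p under 0.05. For fatty acid oxidation the estimated correlation was 0.010, as in the preset, yet its camera adjusted p went from 0.0109 to 0.397. That loss did not come from a higher correlation, so this setting changed more than the correlation. The estimated correlation was 0.025 for NRF2 targets and 0.029 for both the secreted inflammatory and the G1/S list. It was higher for G2/M genes (0.096) and histones (0.39). How far correlated genes account for the other losses cannot be told from this setting. At the preset correlation, adjusted p-values of the lists that did not pass lay between 0.0531 and 0.979. The median, the mean and the direction of the test differed in sign for 8 lists, none of which passed: AMPK upstream and mTORC1 pathway components, lysosome and autophagy, ribosome biogenesis and MYC targets, interferon response, unfolded protein response and heat shock, BMP targets, imprinted growth genes, and neural and glial markers. The rotation test fry called 9 lists, 4 of them also called by camera. The other 5 were the AMPK subunits (adjusted p = 0.0209) and the transition genes (0.00858), both higher, and p53 targets (0.0175), macrophage and leukocyte markers (0.0175) and epithelial and keratinocyte markers (0.0216), all lower.

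Genes of several chromosomes moved together, a comparison added after the data were examined. Over 11164 genes above background, grouped by their chromosome in GRCm38.p6, the median log2 change was 0.25 on chromosome 12, 0.20 on chromosome 19 and 0.13 on chromosome 4. It was -0.14 on the X chromosome, -0.10 on chromosome 15, -0.097 on chromosome 5 and -0.078 on chromosome 11. Against 10000 random gene sets of the same size matched on mean expression, these 7 of the 20 chromosomes passed (two-sided permutation test, adjusted p = 0.000286 for each, from p = 1e-04, the smallest these permutations can give). On chromosome 12, 96 of 371 genes rose and 7 fell, and on the X chromosome 14 of 377 rose and 78 fell. Each Ube2o shRNA array showed these shifts: the median on chromosome 12 was between 0.24 and 0.25 on all 3, while the control arrays lay between -0.014 and 0.020 on the 6 autosomes. On the X chromosome the Ube2o shRNA arrays lay between -0.17 and -0.091, and the controls between -0.036 and 0.040. Ube2o lies on chromosome 11. The direction of all 7 medians was kept under each of the 16 alternatives tried, median scaling included. Subtracting the median of each chromosome gave 2022 probes past the threshold, 798 higher and 1224 lower. Of the genes named by the fixed rule, 12 no longer passed then, while their standard errors (0.11 to 0.14) stayed the same. For Rragc on chromosome 4, Pdia6, Psmc1 and Rrm2 on 12 and Fads1, Pgam1, Scd1 and Scd2 on 19, log2 changes of 0.41 to 0.59 became 0.17 to 0.38. The log2 changes of Ebp on the X chromosome (-0.53 before, -0.39 after), Irf1 on 11 (-0.45, -0.37) and Krt7 on 15 (-0.44, -0.34) became smaller too, and Nes, on chromosome 3, which did not pass as a group, went from 0.51 to 0.49 with an adjusted p from 0.0408 to 0.0519.

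**Figure D4:**
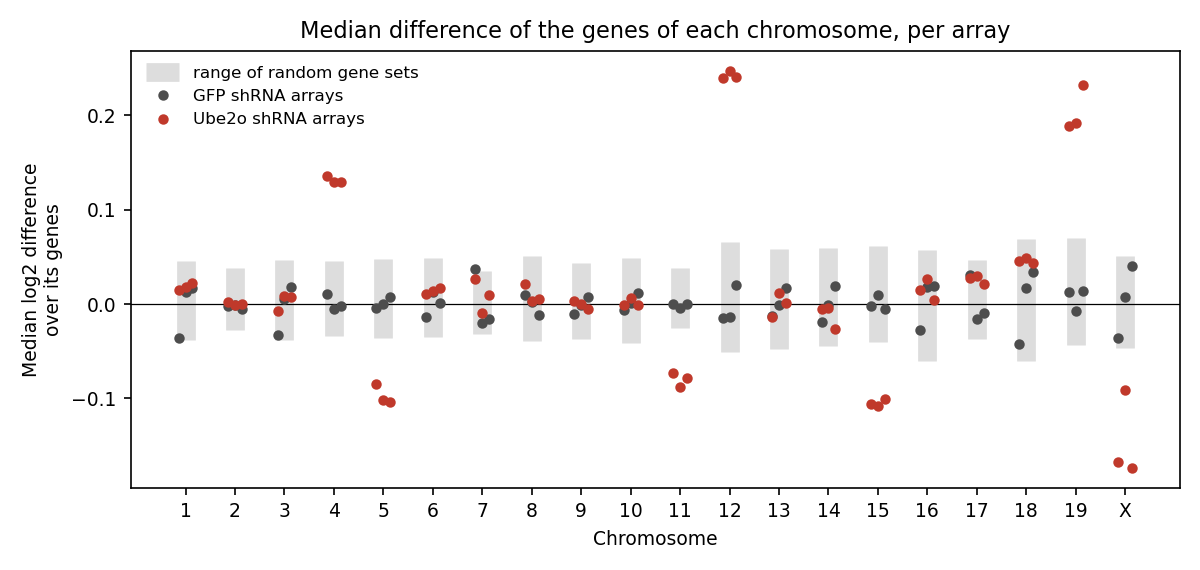
Median log2 difference from the control arrays (vertical axis) over the genes of each chromosome (horizontal axis), with a point per array; each control array is set against the other controls, and grey bars span the medians of 10000 random gene sets. The Ube2o shRNA arrays lay between 0.24 and 0.25 on chromosome 12, and outside the grey bars on chromosomes 4, 5, 11, 12, 15, 19 and X.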

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

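Of the 21 alternatives, normexp at the offset of 16, the filters on inferred background and the subtraction of chromosome medians were chosen after the data were examined. That offset had been planned for neqc, the main setting set out beforehand. The neqc correction with offset 50 and the filter on detection p under 0.01 were not run, since they need detection p-values, not used here. The Ube2o change lay between -1.54 and -1.35 and passed under every alternative that refitted it. The 2236 probes became 3966 with no background correction, 3941 in the series matrix values, 3452 and 3672 with filters on inferred background, 584 with the offset of 16, 965 at 1.5-fold or more and 1295 genes with probes averaged. Leaving out each array gave 1445 to 1682 probes, the fewest without GFP shRNA replicate 1. Filters leave fewer probes to adjust over, averaging counts genes and a larger offset compresses dim probes by construction; otherwise the cause was not tested. The count of lists lay between 4 and 9, except for 0 with an estimated correlation. Some settings added lists to the 6 called. With chromosome medians subtracted 9 passed, 4 higher and 5 lower. With no background correction, and in the series matrix values, 7 passed, 3 higher and 4 lower. Leaving out each array gave 5 to 7 lists. The replicate number as a block gave 2139 probes and 6 lists. Arrays of the same number had correlations of deviations of 0.016, -0.082 and 0.044, within the range of unlike numbers (-0.095 to 0.076). This gives no sign that the numbers pair the arrays, but cannot exclude it. A value past the threshold in neither setting has no called direction and is counted as kept. Of 114 called named genes other than Ube2o, 58 kept their call under every alternative that refitted them (16 or 17 for each), 56 lost it under at least 1, 56 of them with the offset of 16, 17 with median scaling and 12 with chromosome medians subtracted, and 0 reversed. None of the 6 called lists kept its call under all: the secreted inflammatory list lost it only with an estimated correlation, the NRF2 targets also with the stricter filter (adjusted p = 0.0787), and fatty acid oxidation also with that filter (0.0758) and averaged probes (0.0604). With fry, the histones (0.122) and G2/M genes (0.0951) did not pass. Over the alternatives, adjusted p-values of these lists ranged from 8.7e-07 to 0.397 for the secreted inflammatory list, 0.000674 to 0.397 for G1/S, 0.00249 to 0.552 for G2/M, 0.000324 to 0.397 for NRF2, 0.0012 to 0.397 for fatty acid oxidation and 2.44e-05 to 0.652 for histones. Signal near background limits the dim genes, Prkaa2 among them.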

Other observations

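The next genes by size of change, ranks 13 to 30 in each direction, were looked at after the named genes were seen. Among the falls, the gene of the CD47 receptor, Sirpa, fell by 2.34 on the log2 scale, the log2 changes of the MHC class II chaperone gene Cd74, the death receptor gene Tnfrsf21 and the extracellular superoxide dismutase gene Sod3 were -2.17, -1.89 and -1.76, and the hemoglobin scavenger haptoglobin, Hp, was at least 2.84-fold lower. The vitamin D receptor gene Vdr fell by 2.09, and the matrix genes Adamts9 and Fbln1 had log2 changes of -1.95 and -1.73. Among rises, the helix-loop-helix inhibitor Id2 had a log2 change of 1.13, the cyclic GMP-dependent kinase gene Prkg1 1.10, the adhesion gene Nectin3 1.09, the pro-apoptotic BCL2 family gene Bok 1.05 and the sarcoglycan gene Sgcb 0.98. All of these passed limma, with adjusted p-values between 3.2e-10 and 8.79e-05.

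Of the tests that follow, those on chromosomes as groups and on leukocytes were chosen after the pattern was seen. The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The split by shRNA gave 2236 probes and 6 lists, and it was the 1 split with as many of each; the highest of the other splits was 0 probes and 2 lists.

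The genes of chromosomes 4, 12 and 19 were higher and those of 5, 11 and 15 lower as groups. Random matched gene sets argue against a chance of gene sampling (permutation test, adjusted p = 0.000286). These chromosomes were picked by that same test, which takes genes as independent. A single cluster of co-regulated genes would shift only a part of a chromosome. Split at the middle of the gene order, the weakest part still moved by 0.064 in the chromosome's direction. Clusters in both parts are not excluded by this split. An expression-level bias is argued against by the smallest shift of an expression class, 0.039 in the chromosome's direction, and a deviating array by the weakest median without 1 array, which was 0.907 of that with all. In runs of 40 genes by gene order, where the last run of a chromosome holds fewer and is counted from 20 genes, all 16 runs of chromosome 4, all 9 of 12 and all 10 of 19 were above 0, and all 18 of chromosome 5, all 11 of 15 and 22 of the 23 of 11 below 0, the other of 11 at 0.0027; the last 8 genes of chromosome 15, too few to count, had a median of 0.14. A candidate explanation is a difference in chromosome copy number between the cultures, carried by all 3 Ube2o shRNA arrays, which no DNA measurement here tests. An effect of lower Ube2o or of the hairpin on whole chromosomes stays open too, untested. On chromosome 12 the 3 Ube2o shRNA arrays lay between 0.24 and 0.25. Whether their cultures share a history from before they were parted is not known. In that case the p-values would not measure the spread between independent cultures.

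The X chromosome differed from the autosomes in this. The test against random sets gave an adjusted p of 0.000286, the smallest shift of an expression class was 0.048 downwards and the weakest median without 1 array was 0.901 of that with all, which argues against sampling, expression level and a deviating array. Its later part by gene order, however, had a shift of -0.020 in the chromosome's direction, that is, a slight rise, so a regional cause remains open. Along the gene order the first 6 runs of 40 genes had medians from -0.35 to -0.19 and the 3 that followed from 0.070 to 0.092, while the last 17 genes had a median of -0.011. The subtraction above used the median of the whole X chromosome (-0.14). It was therefore too small for the first runs and of the wrong direction for those that followed. Timp1 and Ebp lost their calls with it, while Ndufa1 (-0.69 after) and Ube2a (-0.42 after), also X-linked, kept theirs. No DNA was measured here, so whether the copy number of part of the X chromosome differed was not tested.

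For the secreted inflammatory genes, fewer leukocytes in the Ube2o shRNA cultures were weighed as the source. Of 17 macrophage and leukocyte markers, 5 lay above background on all 3 control arrays: Cd74, Aif1 and Cd14, which fell, and Lyz1 and Lyz2, which did not pass (log2 changes of -0.030 and -0.19). The other 12, Ptprc, Tyrobp and the C1q genes among them, did not, and since probes of different genes differ in sensitivity this excludes no share of such cells, which stays open. After subtraction of the chromosome medians 7 of the 8 genes that fell still passed. Most of these falls were far larger than the medians subtracted. This argues against the direct shift of their own chromosomes as the source of the whole set. Indirect effects of a chromosome-wide difference are not removed by the subtraction and were not tested. At least 6 of the genes passed without any 1 array, which argues against a deviating array. All 3 Ube2o shRNA arrays carry the same hairpin label, so an effect of the hairpin on other genes cannot be told apart from that of lower Ube2o. Either effect, and a difference between the cultures that arose apart from Ube2o, stay open, untested.

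For the G1/S and DNA replication genes, chromosome-wide shifts were weighed. The median of the list was 0.18 before and 0.16 after subtraction of the chromosome medians, and the list still passed camera (adjusted p = 0.00112). This argues against the direct shift of the genes' own chromosomes as the whole source. Indirect effects of a chromosome-wide difference on these genes are not removed by the subtraction and were not tested. The call of the list was lost with median scaling (adjusted p = 0.0808) and, before that subtraction, with an estimated correlation (adjusted p = 0.397).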
